A study of Mus musculus with 20 samples.

How the data were processed

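The series measured N6-methyladenosine (m6A), the most abundant internal mark of messenger RNA, in mouse thymocytes. Cells were sorted from wild-type C57BL/6 mice and from mice in which floxed Mettl3 was deleted by a Cre recombinase under Cd4 control. Mettl3 encodes the catalytic subunit of the m6A writer complex. The series holds 20 sequencing libraries in 8 groups. Invariant natural killer T (iNKT) cells gave 12 libraries, with 3 replicates for each combination of genotype and library type, input or m6A immunoprecipitation. CD4 and CD8 double-positive (DP) thymocytes gave 8 libraries, with 2 replicates for each combination. Per the labels, mice were 6 to 8 weeks old, and polyadenylated RNA was broken into pieces of about 150 nt before immunoprecipitation. The labels' protocols name m6A-seq and a low-input version built on LACE-seq, without saying which cell type was handled by which, so protocol and cell type may coincide.

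Per the submitters' processing notes, the tools were FastQC 0.11.5, Trim Galore 0.6.5, STAR 2.6.0a, RSEM 1.3.0 and HOMER 4.9.1, and the genome build was mm10. The peak caller, its version and the pooling of replicates are not given in the sources used here; the column names of the peak tables are those written by the exomePeak package. The authors deposited 1 table of peaks per cell type that compares the genotypes. Per the file headers, each row of the authors' deposited table gives a spliced interval, a p-value for the peak, a fold enrichment of immunoprecipitate over input as a linear ratio, and a log2 fold change of methylation between genotypes. Per the file headers, it also gives the log10 of the p-value and of the false discovery rate (FDR), for the peak and for the difference, which are treated as scores. A gene symbol, an Ensembl identifier and a position class come from the authors' annotation, per the file headers. The authors also deposited a list of genes per cell type. Counts per library were not analysed here, so the depth of each library is unknown, no spread between replicates can be given, and the differences below cannot be set against such a spread. The p-values are the authors' own. It is unknown how far they take in variation between mice.

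The sign of the log2 fold change is not stated. A negative value is taken as likely lower methylation in Mettl3-deleted cells, on the basis that the deposited gene lists hold nearly all genes with a negative peak and that the deletion removes an m6A writer. From here on lower and higher refer to this likely direction. Mettl3 itself has no peak in either table, and its transcript was not measured here, so the deletion could not be checked.

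Rows with the same coordinates, strand and blocks were kept 1 time, which removed 5 rows from the DP table and 24 from the iNKT table. A peak passed at a differential FDR of 0.05 and was counted by its sign. Shares have Wilson 95% confidence intervals, and medians have intervals from the ranked values by the binomial distribution. Ratios and differences in the tests of causes have bootstrap intervals from 2000 draws. Genes were compared between cell types with Fisher's exact test (two-sided) over genes with a peak in both tables. Peaks were matched with bedtools 2.31.1 by at least 1 shared exonic base on the same strand. The exact McNemar test over the same matched peaks compares the tables and not the cell types, because peaks are not independent replicates, and correlations across peaks have permutation p-values from 100000 draws. Lists of genes were tested with Fisher's exact test (two-sided) for genes with a passing lower peak among genes with any peak, with Benjamini-Hochberg adjustment over the 12 lists of a table. Because genes with more peaks pass more often, each list was also set against 10000 random lists matched on peaks per gene. Positions were taken from the authors' annotation and tested with Fisher's exact test (two-sided) over 18 comparisons. In it, exon stands for exons outside the class of untranslated regions (UTRs). A test of the sequence motif, and positions from a separate annotation, were planned and not run because no genome or transcript models were used here. No count model was run, because the tables hold no counts per library. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

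The list test was tested on simulated data before use, with 400 random lists of 30 genes per table. Lists without an effect were called in 5.0% of draws in DP cells and 4.0% in iNKT cells, and planted lists were called in 100% of draws in each table. With matching on peaks per gene the shares without an effect were 4.75% and 3.25%. The simulation used the same pass rate for both tables, far above the 1.44% of DP genes with a passing lower peak. Its planted effect was also large. It therefore does not give the error rate or the power of the list test at the DP pass rate. The simulated lists were drawn evenly from all genes, so they had no excess of peaks per gene. Some of the lists used have many, such as chromatin regulators with 4.22 peaks per gene in iNKT cells. For such lists the simulation does not give the error rate of the test without matching.

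The lists and the rule for named genes were fixed before the data were examined, as were most tests, while some tests of causes, of families of symbols, of gene spans and of higher peaks in lists were chosen after. The rule takes, per cell type, the 6 genes of each sign with the largest change and the 6 with the smallest differential FDR. It adds up to 4 passing members of each list, the 6 genes lower in both cell types with the most negative mean change, and a fixed set of genes including Mettl3, Creb1, Zbtb16, Rag1, Myc, Socs1 and Il7r. Some genes that the rule takes are not reported here. The lists are the m6A writer complex, m6A readers and erasers with other methyltransferases, iNKT cell development, DP thymocyte identity, T cell receptor signalling, the p53 pathway with apoptosis, cytokine receptors with JAK-STAT and SOCS genes, mTOR with PI3K and glucose metabolism, the cell cycle, chromatin regulators, the CREB family with its coactivators and immediate early targets, and markers of other thymus cell types. Genes on opposite strands that overlap cannot be told apart, because peaks of equal fold change and equal ends on opposite strands occurred for 1 pair in DP cells and 3 pairs in iNKT cells. Pairs with slightly shifted ends were not counted, so there are more. An example is a pair named Mat2a in iNKT cells, with a log2 fold change of -0.577 on each strand. Gene counts are counts of the symbols of the authors' annotation, which often name a neighbour. A RefSeq table of gene spans (GRCm38.p6, without strands) held the symbol of 99.7% of named peaks in each cell type, and 21.4% of named peaks in DP cells and 25.2% in iNKT cells lay outside the span of that gene. Of the passing peaks chosen by the rule, 8 of 37 in DP cells and 11 of 76 in iNKT cells lay outside, and those reported are given with the RefSeq gene they overlap. Lists and gene overlaps were run again with only peaks within the gene they are named after, on the strand of most such peaks. Alternatives changed the FDR threshold, the minimum change, the strength of the peaks, the overlap rule, the unit counted and the matching of lists.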

Results

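The data describe m6A in 2 sorted thymocyte populations, each compared between wild-type and Mettl3-deleted cells. DP thymocytes are the CD4 and CD8 expressing stage at which the T cell receptor alpha chain is rearranged. The iNKT cells, which recognise lipids on CD1d, are a T cell lineage that branches off from DP thymocytes. DP cells were represented by 2 replicates and iNKT cells by 3 replicates per genotype and library type. After repeated rows were removed, the authors' deposited table for DP cells held 13450 peaks in 6618 genes, and that for iNKT cells held 12542 peaks in 6774 genes. Peaks had a median exonic length of 241 nt in DP cells and 181 nt in iNKT cells. Median fold enrichment over input was 4.7 (quartiles 2.83 and 9.12) in the authors' deposited table for DP cells. It was 8.32 (quartiles 4.26 and 20.9) in the authors' deposited table for iNKT cells. The fold enrichments and fold changes are the authors' own values, and coordinates are on mm10. The tables hold no values per replicate.

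The first comparison asked how m6A differed between Mettl3-deleted and wild-type DP thymocytes. Few DP peaks differed, and those that did changed by small amounts. Of 13450 peaks, 100 were lower and 65 were higher in Mettl3-deleted cells at an FDR of 0.05 in the authors' deposited table, 1.23% of peaks together. The lower peaks lay in 95 genes and the higher peaks in 58, with 1 gene, Bcl11b, in both sets. Their median log2 fold changes in the authors' deposited table were -0.47 and 0.60. The lower peaks made up 60.6% of those that passed (95% confidence interval 53% to 67.7%). At least 2-fold changes were found for 10 of the lower and 23 of the higher peaks. With the sign of the DP table turned, which stays possible, the lower share would be 39.4% (32.3% to 47.0%), and 23 of the 33 larger changes would be falls.

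The lower DP peak with the smallest FDR lay in Myh9, which encodes a heavy chain of non-muscle myosin. It fell by 0.522 on the log2 scale in the authors' deposited table (FDR 2.2e-10, exon, chromosome 15, 77763850 to 77765503). Peaks in Ezr, which encodes the membrane-cytoskeleton linker ezrin, and Stmn1, which encodes the microtubule regulator stathmin, had log2 fold changes of -0.204 and -0.303 in the authors' deposited table. Peaks in Rpl19, a ribosomal protein gene, Def6 (named Ppard by the authors' annotation) and Hsp90ab1, a chaperone gene, had -0.321, -0.286 and -0.264 in the authors' deposited table. The largest falls were in Atad5 (-4.17, FDR 0.03), Ska2 (named Trim37; -2.57, FDR 0.043) and Fignl1 (-2.36, FDR 0.045) in the authors' deposited table, all on chromosome 11. Atad5 acts in unloading the replication clamp, and Fignl1 in homologous recombination. AI662270, Sh3bgrl (named Gm6377) and Tlk2 followed with log2 fold changes of -1.74, -1.32 and -1.26 in the authors' deposited table.

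Higher DP peaks included transcripts that define this stage. Rag1, which encodes a subunit of the recombinase of antigen receptor genes, rose by 0.151 in the authors' deposited table over a 2064 nt stretch of its exon 2 (FDR 3.7e-05, chromosome 2, 101641690 to 101643753). Satb1, a genome organiser of thymocytes, rose by 0.161 in the authors' deposited table (FDR 0.03). Bcl11b, a T lineage transcription factor gene, had a higher 3' UTR peak (0.276, FDR 0.00018) and a lower 5' UTR peak (-0.304, FDR 0.032) in the authors' deposited table. Malat1, an abundant nuclear non-coding RNA, rose by 0.325 in the authors' deposited table (FDR 4.1e-06). The largest rises were in Ssh2 (2.58), Tmie (named Prss50; 2.33), Gna12 (named Amz1; 2.27), Cdv3-ps (named Gm10377; 2.13), Rxrb (2.03) and Cry2 (named Mapk8ip1; 1.96) in the authors' deposited table. A peak in Prdm2, which the annotation names Mir7021, rose by 1.0 in the authors' deposited table (FDR 0.00019).

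No list of genes was enriched for lower DP peaks after adjustment over the 12 lists. Chromatin regulators came closest, with 3 of 37 genes (Crebbp and Smarca4 among them; unadjusted p = 0.016, adjusted p = 0.19, Fisher's exact test), against 6 adjusted over the list alone. Crebbp, which encodes a histone acetyltransferase that binds CREB, fell by 1.09 on the log2 scale in the authors' deposited table. iNKT cell development genes had 2 of 29 (adjusted p = 0.27), DP identity genes 2 of 30 (adjusted p = 0.27) and T cell receptor signalling genes 1 of 32 (adjusted p = 0.64). Their lower counts were 2, 3 and 2 when adjusted over the list alone. The members were Bcl11b and Myb for iNKT development and for DP identity. Cytokine and JAK-STAT genes had 1 of 19 (Il2rg), the cell cycle 1 of 18 (Mcm2) and the CREB family 1 of 19 (Crebbp), each at adjusted p = 0.48 (Fisher's exact test). Adjusted over the list alone, these counts were 2, 2 and 1. No lower peak passed, overall or adjusted over the list alone, in 7 writer complex genes, 9 reader and eraser genes, 17 p53 pathway genes, 12 mTOR and PI3K genes or 6 markers of other thymus cell types. The upper confidence limits of these shares of 0 were 35.4%, 29.9%, 18.4%, 24.2% and 39.0%. DP identity genes had higher peaks in 3 of 30 (Bcl11b, Rag1 and Satb1, adjusted p = 0.026, Fisher's exact test), with 6 adjusted over the list alone. This was lost with matching on peaks per gene (adjusted p = 0.1, permutation), though not when only peaks within the named gene were matched (adjusted p = 0.043). At an FDR of 0.01 Satb1 no longer passed, and the call then rested on 2 genes (adjusted p = 0.047, Fisher's exact test, without matching).

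The same comparison in iNKT cells gave many more changes, with lower peaks in the majority. Of the iNKT peaks, 2488 were lower and 733 were higher in Mettl3-deleted cells in the authors' deposited table, 25.7% of 12542 peaks together. Lower peaks made up 77.2% of those that passed (95% confidence interval 75.8% to 78.7%). They lay in 1775 genes, 26.2% of those with a peak, while higher peaks lay in 653 genes, and 166 genes had both. The median log2 fold change in the authors' deposited table was -3.64 among lower peaks and 5.04 among higher peaks, and 2445 of the lower peaks changed at least 2-fold.

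The deepest falls included Zbtb16, which encodes PLZF, the transcription factor that directs the iNKT effector programme. A 419 nt peak in its exon 2 had a log2 fold change of -8.43 in the authors' deposited table (FDR 3.2e-60, chromosome 9, 48832143 to 48832561). A second Zbtb16 peak, in the 5' UTR, fell by 3.12 in the authors' deposited table. A peak in Pik3r5, a regulatory subunit gene of phosphoinositide 3-kinase gamma, which the annotation names after its neighbour Pik3r6, had the most negative value of the authors' deposited table (-9.55). Zc3h18, the elongation factor gene Supt5, the chaperone gene Hsp90aa1 and Trim44 followed with -9.00, -8.92, -8.84 and -8.44 in the authors' deposited table. The smallest FDRs included those of lower 3' UTR peaks of Rbm25, a splicing regulator, Anp32a, Anp32b (named Nans), and Hmgb2, a chromatin protein gene, with log2 fold changes of -6.13, -5.95, -5.35 and -5.05 in the authors' deposited table. A peak annotated as Mir6948, which also overlaps Acin1, fell by 4.84 in the authors' deposited table.

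Higher iNKT peaks had a median exonic length of 179 nt, against 271 nt for lower peaks. Eef1a1, which encodes translation elongation factor 1 alpha, had a log2 fold change of 11.3 in the authors' deposited table, over 60 nt of its 5' UTR (chromosome 9, 78480768 to 78480827). Eef2, which encodes elongation factor 2, and Rps14, a ribosomal protein gene, rose by 6.46 and 4.53 in the authors' deposited table, also in the 5' UTR. A peak annotated as Snord37, which lies in exon 2 of Eef2, rose by 3.71 in the authors' deposited table. Peaks in Rn45s, the ribosomal RNA precursor, and Lars2 rose by 7.43 and 8.59 in the authors' deposited table. The authors' deposited table gave a peak named Lrrc4c, which overlaps no RefSeq gene, a rise of 6.30. The peaks named Eef2, Snord37 and Lrrc4c were weakly enriched over input (1.53, 1.69 and 1.33 in the authors' deposited table). The largest value of the authors' deposited table was in Kif21b, a kinesin gene (12.5, FDR 1e-105), over 60 nt. Its fold enrichment over input was 2.06, against a median of 5.04 among higher iNKT peaks. The next largest rises were in Fbxo42 (named Cplane2), Dnajc17 (named Gm14137), Atp6ap1 and Ptbp3, with 10.5, 10.5, 10.4 and 10.3 in the authors' deposited table. Kif21b and Ptbp3 also had passing lower peaks. Rn45s is present in many copies, so the origin of its reads is uncertain.

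Cytokine receptor, JAK-STAT and SOCS genes had the highest share of lower peaks among lists of over 10 measured genes. In this list 17 of 21 genes (81.0%) had a lower peak in iNKT cells, against 26.03% of other genes (odds ratio 12.1, adjusted p = 1.4e-06, Fisher's exact test), and 17 adjusted over the list alone. Il4ra, Smad2, Ifnar1 and Stat6 had log2 fold changes of -6.84, -6.42, -5.63 and -5.11 in the authors' deposited table. Il7r, which encodes the interleukin-7 receptor alpha chain, had 4 passing peaks, with log2 fold changes of -3.07, 2.26 and -1.19 in the 3' UTR and -1.88 in the 5' UTR in the authors' deposited table. The only iNKT peak within Socs1, a cytokine signalling inhibitor gene, did not pass (-0.716 in the authors' deposited table), and the others named after it lay in Clec16a. Chromatin regulators had lower peaks in 26 of 36 genes (72.2%, adjusted p = 1.1e-07, Fisher's exact test), with 27 adjusted over the list alone. Among them the histone methyltransferase gene Kmt2d had a log2 fold change of -7.74 and the demethylase gene Kdm5a -6.56 in the authors' deposited table, and a peak in Kmt2c rose by 8.95. Kmt2d and Kmt2c each had passing peaks of both signs. In the CREB list 16 of 22 genes (72.7%, adjusted p = 2.6e-05, Fisher's exact test) had a lower peak, and 16 adjusted over the list alone. Its members included the immediate early genes Fosb (-6.15) and Jun (-5.80) and the coactivator gene Crebbp (-6.22) in the authors' deposited table, and Fosl2 had a higher peak (7.05) besides a lower one. The only Creb1 peak had a log2 fold change of -0.072 in the authors' deposited table and did not pass (FDR 0.76).

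Genes of iNKT cell development had lower peaks in 18 of 34 (52.9%, adjusted p = 0.0036, Fisher's exact test), with 20 adjusted over the list alone. Besides Zbtb16 they included S1pr1, a receptor for thymic exit (-6.92 in the authors' deposited table), Tbx21, Gata3, Egr1 and Klf2. Gata3 also had a passing higher peak. Myc had 2 lower peaks, of -4.58 and -1.84 in the authors' deposited table. In the authors' deposited table Runx3 and Runx1 carried higher peaks of 8.20 and 7.58 (Runx3 also a lower one), and Cd1d1, which encodes the molecule that presents lipids to iNKT cells, a higher 3' UTR peak of 5.40. mTOR and PI3K genes had lower peaks in 9 of 14 (64.3%, adjusted p = 0.0073, Fisher's exact test), with 9 adjusted over the list alone. Pik3r1 and Foxo3 had -6.55 and -6.43 in the authors' deposited table, and Pik3ca and Akt1 had higher peaks of 8.94 and 5.91. Foxo3 also had a passing higher peak and Pik3ca a passing lower peak. T cell receptor signalling genes had lower peaks in 16 of 32 (adjusted p = 0.0080, Fisher's exact test), with 17 adjusted over the list alone. Plcg1 and Nfatc1 had -6.08 and -5.05 in the authors' deposited table, and Malt1 and another peak of Nfatc1 were higher. Of the m6A writer complex, 5 of 6 genes (Cbll1, Rbm15, Rbm15b, Virma and Zc3h13, adjusted p = 0.0099, Fisher's exact test) had a lower peak, and 5 adjusted over the list alone. Zc3h13 had -6.97 in the authors' deposited table and Rbm15b -4.57, while a peak of -6.29 named Rbm15b lay in Dcaf1. With random lists matched on peaks per gene, the adjusted p was 0.094 for the writer complex and 0.067 for T cell receptor signalling, so these calls were lost, and the other 5 lists stayed at or under 0.050 (permutation). When only peaks within the gene they are named after were counted, the same 7 lists passed, but with matching added mTOR and PI3K genes (7 of 12) did not (adjusted p = 0.14, permutation). From other genes to matched lists as the reference, the excess of chromatin regulators went from 2.78 to 1.47 times, that of the CREB list from 2.79 to 1.65 times and that of the writer complex from 3.19 to 2.04 times. No list was matched on the strength of its peaks, which went with passing. The passing share of iNKT peaks was 3.8% in the weakest bin of peak p and 68.5% in the strongest. How far this adds to the excess of the lists was not tested.

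The remaining lists were not enriched for lower iNKT peaks. DP identity genes had 12 of 28 (adjusted p = 0.079) with 13 adjusted over the list alone, and Rag1 fell by 3.87 in the authors' deposited table. Readers and erasers had 4 of 11 (Ythdc1, Hnrnpc, Pcif1 and Hnrnpa2b1, adjusted p = 0.54, Fisher's exact test), and 4 adjusted over the list alone. The reader gene Ythdc1 fell by 5.49 in the authors' deposited table. p53 pathway genes had 5 of 21 (adjusted p = 1, Fisher's exact test), and 5 adjusted over the list alone, with Bbc3 at -4.58 in the authors' deposited table, while Ei24 and Bcl2l1 rose by 6.75 and 6.34. A peak named Bid (-4.52 in the authors' deposited table) lay in its neighbour Bcl2l13, and with peaks within the named gene only, the count was 3 of 19. The cell cycle list had 2 of 16 (Ccnd2 and E2f2, adjusted p = 0.36, Fisher's exact test), and 2 adjusted over the list alone. Ccnd2 and E2f2 had -4.19 and -1.96 in the authors' deposited table. None of 6 markers of other thymus cell types had a passing peak of either sign, overall or adjusted over the list alone (adjusted p = 0.42, Fisher's exact test, upper confidence limit of the lower share 39.0%). Higher peaks passed in 4 lists before matching: DP identity with 8 genes (adjusted p = 0.023), the CREB list with 7 (adjusted p = 0.023), mTOR and PI3K with 5 (adjusted p = 0.024, Fisher's exact test) and chromatin regulators with 9 (adjusted p = 0.024). With matching on peaks per gene none of these 4 passed (adjusted p = 0.27, 0.33, 0.27 and 0.8, permutation), so they may only reflect genes with many peaks. Dtx1 and Gfi1 of the DP identity list had higher peaks of 8.46 and 7.81 in the authors' deposited table, and Dtx1 also had a passing lower peak. The Gfi1 peak lay on the strand opposite to that of its other peaks.

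**Figure D1:**
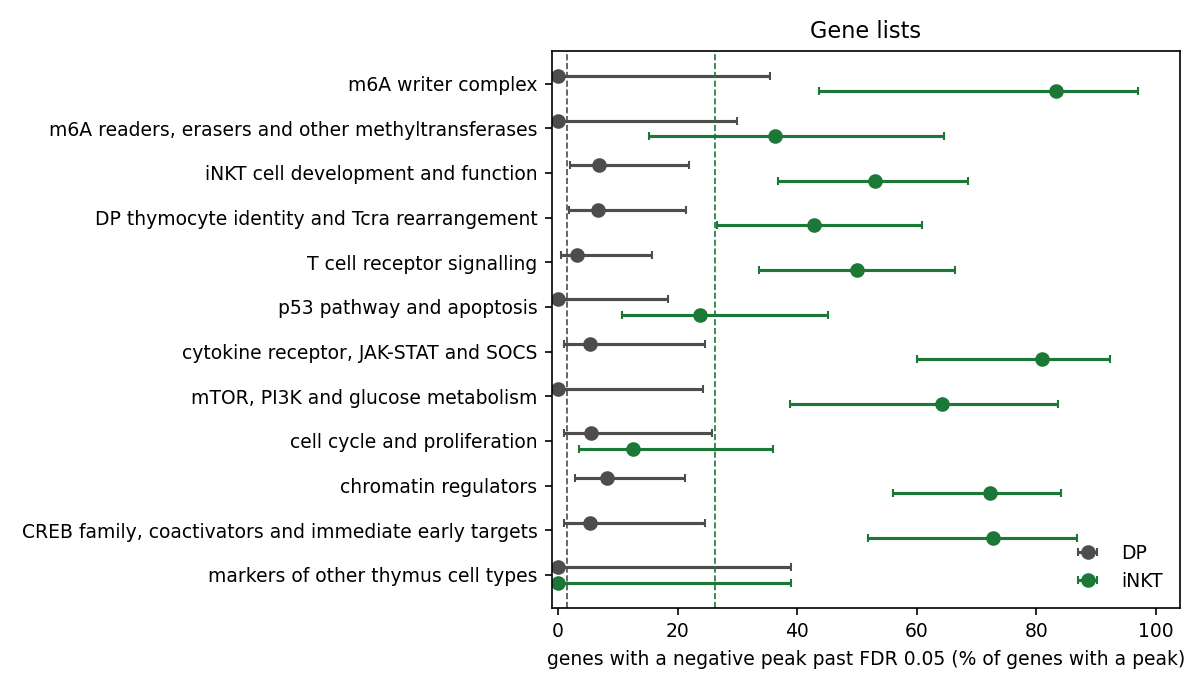
Share of genes with a lower (negative) peak past FDR 0.05, in percent of the list's genes with a peak, for DP and iNKT cells; points are shares, bars are Wilson 95% confidence intervals and dashed lines are all genes with a peak (1.44% in DP and 26.2% in iNKT). Cytokine and JAK-STAT genes reached 81.0% in iNKT cells and 5.26% in DP cells. With the sign of the DP table turned, 0 of these 19 genes would have a lower peak in DP cells.

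Over all peaks the log2 fold changes centred on 0 in DP cells and below 0 in iNKT cells. The median in the authors' deposited table was 0.0 for DP cells (quartiles -0.39 and 0.42). For iNKT cells it was -0.98 in the authors' deposited table (quartiles -2.32 and 0.26, 95% confidence interval of the median -1.0 to -0.92). A negative value was listed for 49.7% of DP peaks and 68.6% of iNKT peaks. In iNKT cells the quintile of the most enriched peaks had a median of -2.13 in the authors' deposited table, the weakest quintile -0.26 and the next 0.0. In DP cells the medians of the quintiles lay between -0.088 and 0.045 in the authors' deposited table. Of the lower DP peaks, 53 lay in the weakest quintile and 0 in the strongest, and of the higher DP peaks 9 and 8.

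**Figure D2:**
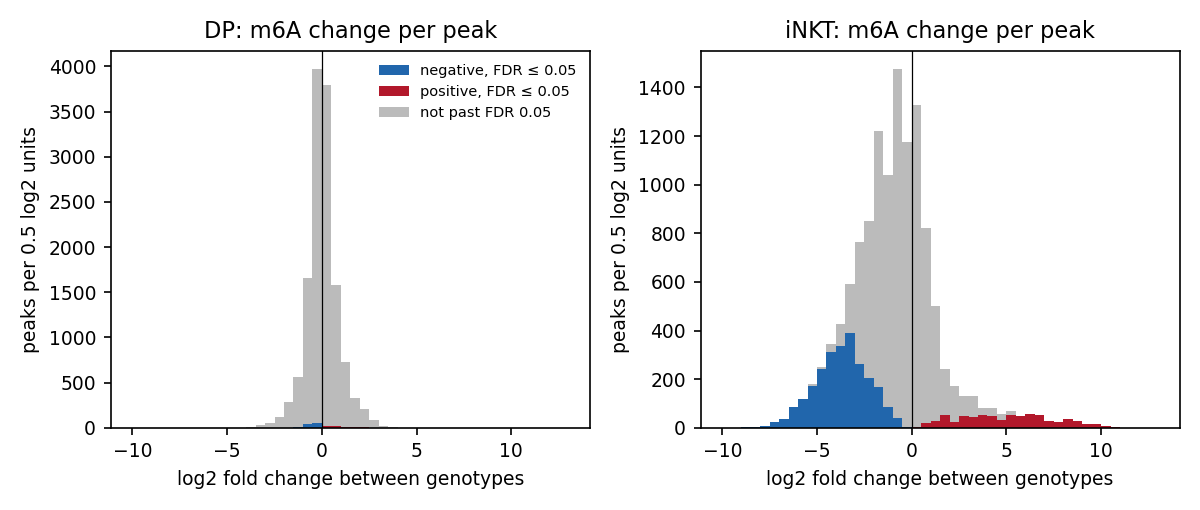
Number of peaks per 0.5 log2 units (vertical axis) by log2 fold change between genotypes (horizontal axis), for DP and iNKT cells, with stacked colours for peaks lower (negative) or higher (positive) past FDR 0.05 and grey for the rest. The iNKT values spread from -9.55 to 12.5 and the DP values from -4.17 to 3.75.

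**Figure D3:**
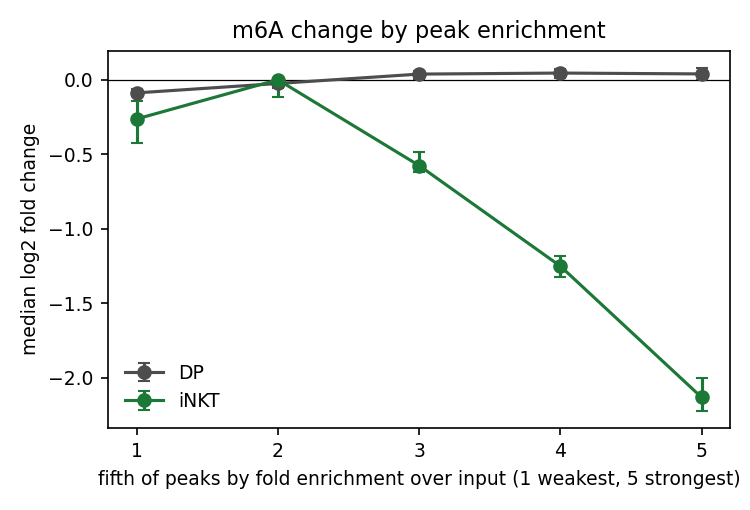
Median log2 fold change (vertical axis) in each quintile of peaks ordered by fold enrichment over input (horizontal axis, 1 weakest), for DP and iNKT cells. Bars are 95% confidence intervals from the ranked values by the binomial distribution. The iNKT median went from -0.26 in the weakest quintile to -2.13 in the strongest, with 0.0 in the next weakest.

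Lower and higher peaks differed in their place along the transcript within each table. The tests count each peak, and peaks are not independent replicates, so their p-values and intervals describe the tables and not a spread between mice. In iNKT cells 50.6% of lower peaks lay in 3' UTRs against 43.9% of all other peaks (odds ratio 1.31, adjusted p = 1.7e-08, Fisher's exact test), as for Rbm25 and Hmgb2. Higher iNKT peaks lay in 5' UTRs more often than lower peaks, 20.7% against 10.2% (odds ratio 2.30, adjusted p = 6.4e-12, Fisher's exact test), as for Eef2 and Runx3. In DP cells 28.0% of lower peaks lay in 3' UTRs against 45.6% of all other peaks (odds ratio 0.464, adjusted p = 0.00086, Fisher's exact test). Higher DP peaks lay there in 58.5% (odds ratio 3.59 against lower peaks, adjusted p = 0.00041, Fisher's exact test), as for Satb1. Exons outside UTRs held 59.0% of lower and 24.6% of higher DP peaks (adjusted p = 4.4e-05, Fisher's exact test), Myh9 among the lower. The DP contrasts were lost at an FDR of 0.01 (Fisher's exact test). With 40 lower peaks left, 30% of them lay in 3' UTRs (odds ratio 0.512 against other peaks, adjusted p = 0.14, Fisher's exact test) and 60% in exons. Higher peaks lay in 3' UTRs in 42.3% (odds ratio 1.70 against lower peaks, adjusted p = 0.7, Fisher's exact test) and in exons in 34.6% (adjusted p = 0.16, Fisher's exact test).

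**Figure D4:**
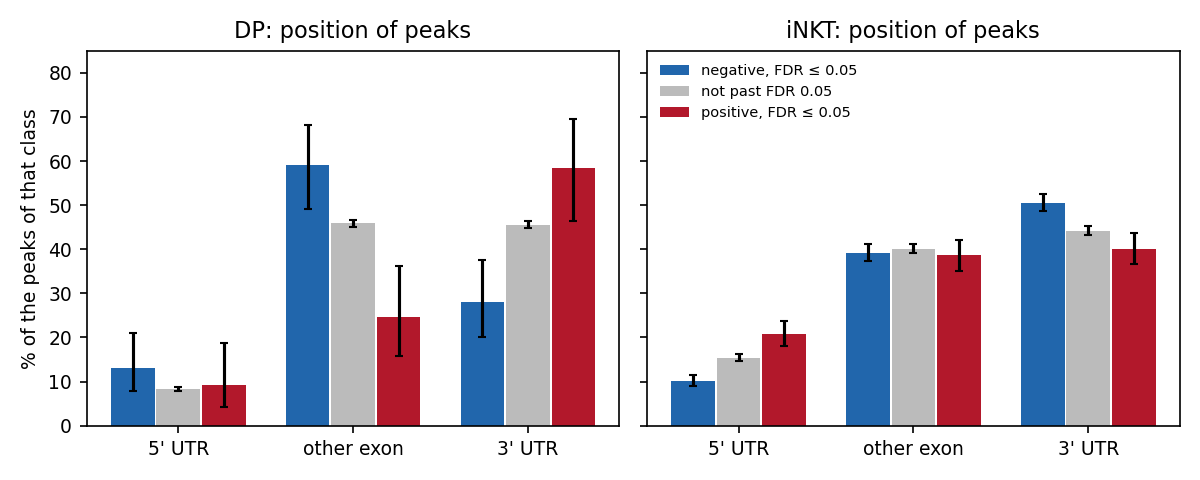
Share of peaks, in percent of the peaks of a class, in the 5' UTR, other exons and the 3' UTR by the authors' annotation, for lower (negative), not passing and higher (positive) peaks of DP and iNKT cells; bars start at 0 and error bars are Wilson 95% confidence intervals. The 5' UTR share of higher iNKT peaks was 20.7%, and that of lower iNKT peaks was 10.2%.

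The last comparison set DP cells against iNKT cells under the same deletion. Among 4389 genes with a peak in both tables, 50 had a lower peak in both, against 27.6 expected (odds ratio 3.44, 95% confidence interval 2.09 to 5.79, adjusted p = 7.7e-07 over 4 tests, Fisher's exact test). They included Crebbp, Bcl11b, Akap13 and Safb2, whose most negative iNKT peak, not always the one that overlaps the DP peak, had a log2 fold change between -6.22 and -5.24 in the authors' deposited table. In DP cells those of Bcl11b and Safb2 were -0.304 and -0.226 in the authors' deposited table. Genes with a higher DP peak also had lower iNKT peaks more often than expected, 36 against 19.99 (odds ratio 3.37, adjusted p = 2.7e-05, Fisher's exact test). For genes higher in both the overlap was 12 against 5.29 (adjusted p = 0.0067, Fisher's exact test), and for a lower DP with a higher iNKT peak it was 9 against 7.31 (adjusted p = 0.44). Matching on peaks per gene was run for genes lower in both, whose number was then 1.53 times that expected, and not for the other overlaps. With peaks within the named gene only, 48 of 3350 genes were lower in both, against 24.4 expected (odds ratio 4.85), and 1.61 times those expected with matching. In that run 12 genes were higher in both, against 3.49 expected (odds ratio 4.70). A higher DP with a lower iNKT peak was found for 23 against 14.2 (odds ratio 2.59), and the reverse for 8 against 5.98 (odds ratio 1.40). The excess was thus not particular to genes lower in both, and no overlap was matched on the strength of peaks. No correlation of the sizes of change was found at matched places. Over 4682 overlapping peaks Pearson's r was -0.0005 (permutation p = 0.97) and Spearman's rho 0.011 (permutation p = 0.44), across peaks, which are not independent replicates. Without the 2 peaks farthest from the median in DP cells, r was -0.0006. The sign was shared by 45.1% of the pairs, against 45.5% expected from the signs of each table.

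At these overlapping peaks 1834 (39.2%) were lower in iNKT cells and 36 (0.769%) in DP cells, and 55 (1.18%) were higher in DP cells. Of the lower peaks, 1807 passed as lower only in iNKT cells and 9 only in DP cells. Peaks lower in both numbered 27, among them Smarca4, Ezr, Stmn1 and Hsp90ab1, and peaks higher in both numbered 5. Another 35 passed with opposite signs. Of them 34 were higher in DP and lower in iNKT cells. Rag1 had 0.151 in DP and -3.87 in iNKT cells in the authors' deposited table, Satb1 0.161 and -2.38, and Supt5 0.339 and -8.92. Jund, an AP-1 transcription factor gene, had 0.335 and -3.18 in the authors' deposited table. Ppp1r12a alone was lower in DP (-0.83) and higher in iNKT cells (1.31) in the authors' deposited table. Libraries of the cell types differ in replicate number and possibly in protocol, so this comparison does not separate cell type from them.

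**Figure D5:**
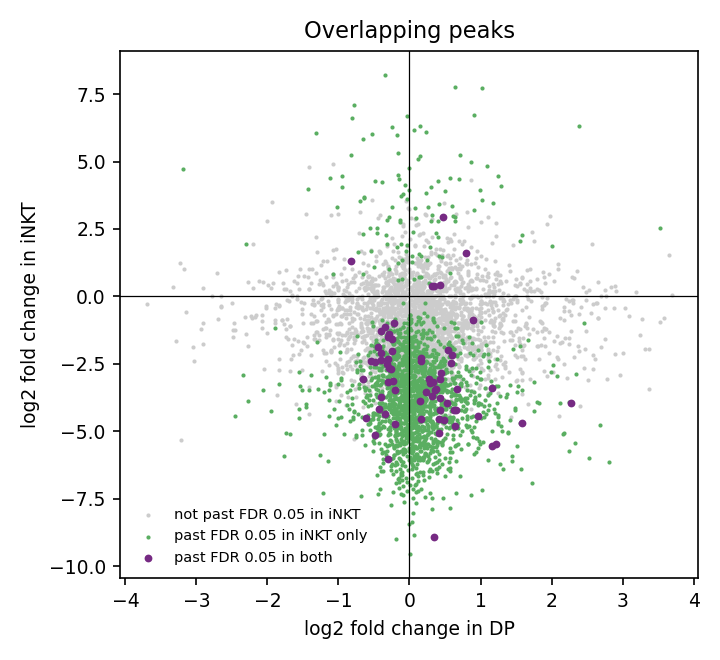
Log2 fold change in iNKT cells (vertical axis) against that in DP cells (horizontal axis) for 4682 overlapping peaks, each point a peak, coloured by whether it passed FDR 0.05 in iNKT cells only, in both or not in iNKT cells. The points form no slope (Pearson's r -0.0005), and 27 peaks were lower in both.

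The deposited gene lists named 4336 genes for DP and 5339 for iNKT cells. All of them had a peak with a negative log2 fold change in the authors' deposited table. Among the listed genes 95 (2.19%) had a passing lower peak in DP cells and 1775 (33.2%) in iNKT cells. The DP list left out 1 gene with a negative peak and the iNKT list 4.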

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

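The test of a hidden loss in DP cells, the test of the DP sign and the share of mitochondrial and translation transcripts were chosen after the results were seen. The other tests were set before.

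Overlapping peaks passed as lower in 39.2% of cases in iNKT cells and 0.769% in DP cells (1.18% if the DP sign is turned), a difference between the tables picked out by an exact McNemar test over peaks, which are not independent replicates, so a difference between cell types was not tested. Stronger peaks in the iNKT table are argued against as the whole cause, because in 6 of 6 bins of similar peak p the passing share in iNKT cells was over 3 times that in DP cells. The strongest bin had no upper limit, so peak strength was not held equal within it. It held 2942 iNKT peaks, 2014 of them passing, and 586 DP peaks. In the bins below it the ratio was at least 6.4. Different sets of transcripts are argued against by the 21.4-fold higher passing share at overlapping peaks. The FDR of 0.05 stands for a smaller unadjusted p in the DP table, so all these shares carry a gap in threshold. Of 13450 DP peaks, 874 were lower and 831 higher at an unadjusted p of 0.05, against 2905 and 873 of 12542 iNKT peaks. The bins and overlapping peaks were not compared at equal unadjusted p. A loss hidden by scaling to library totals is argued against only if graded by peak strength as in iNKT cells. The strongest quintile of DP peaks differed from the weakest by 0.13 in median log2 fold change, against -1.87 in iNKT cells. A smaller hidden loss in DP cells, or one of equal size at all peaks, stays open. Also open and untested are the number of replicates and a biological difference such as the time since the deletion began, which coincide with cell type, and the low-input protocol, which may.

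Higher peaks in Mettl3-deleted iNKT cells, 733 in all, run against the loss of a writer. Mitochondrial, ribosomal and translation factor transcripts held 5.05% of them, which is too few to be the whole cause. Methylation at transcript starts that the Mettl3 complex does not make may contribute, since the 5' UTR share was 2.03 times that of lower peaks, and so may a shift of immunoprecipitated reads to weakly enriched regions, with a median fold enrichment 0.462 times that of lower peaks. The limits set beforehand, over 2 and under 0.5, were met by both estimates, but their intervals (1.67 to 2.41 and 0.415 to 0.517) reach past them. Rare transcripts stay open, although the median log10 peak p of higher peaks (-15.6) lay further from 0 than that of peaks that did not pass (-11.5), because a peak needs reads to pass, which fixes the outcome of that test.

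Of the 91 overlapping peaks that passed in DP cells, 35 passed with the opposite sign in iNKT cells, as for Rag1, Satb1 and Supt5. A DP table coded in the opposite direction would make those with a rise in DP cells the true losses. Against this, the deposited lists hold 4336 of 4337 DP genes and 5339 of 5343 iNKT genes with a negative peak, but what the lists stand for is not stated. Peaks higher in DP cells were lower in iNKT cells in 61.8% of cases (34 of 55) and peaks lower in DP cells in 75% (27 of 36), with p = 0.255 (Fisher's exact test), so the direction of the DP table cannot be told apart from its reverse. A difference between the cell types at these transcripts was not tested.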

How the results depend on the processing

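Merging overlapping peaks, leaving out mitochondrial and translation transcripts, strong peaks only in the overlap of genes, peaks within the gene they are named after, and matching and FDR 0.01 for higher peaks of lists were chosen after seeing the data. No list passed for higher peaks with matching over all peaks. In iNKT cells the counts of passing peaks stayed within 1.5 times under every alternative run (1673 to 2905 lower, 592 to 873 higher). The number of enriched lists did so (5 to 7) when alternatives were taken singly. With matching and peaks within the named gene combined, fewer than 5 lists were left. The mTOR and PI3K list was then lost as well (adjusted p = 0.14, permutation). The excess of genes lower in both cell types held under each alternative run (odds ratio 3.22 to 7.80, and 1.53 times the expected number with matching on peaks per gene). It was not particular to that pair of signs. Genes higher in both were also in excess (odds ratio 2.67, and 4.70 with peaks within the named gene). DP counts depended on the threshold. An FDR of 0.01 left 40 lower and 26 higher DP peaks, an unadjusted p of 0.05 gave 874 and 831, and a change of at least 2-fold 10 and 23. The lower share of 60.6% then became 51.3% with the unadjusted p and 30.3% with the minimum change. Genes on the DP list with a passing lower peak numbered 36 at FDR 0.01 and 764 at the unadjusted p. The DP median was -0.30 over passing peaks and 0.017 over strong peaks, and the iNKT median was -3.16 over passing peaks. Pearson's r over overlapping peaks was 0.0056 when 50% of the shorter peak had to be shared, so its sign, near 0, reversed. At FDR 0.01 the odds ratio of 3' UTR position of lower DP peaks was 0.512 and no longer passed (adjusted p = 0.14, Fisher's exact test), with fewer peaks, and that of 5' UTR position of higher against lower DP peaks reversed to 1.17 (neither passed). The causes of these shifts were not tested. Of 37 named DP peaks 21 no longer passed at FDR 0.01, 23 fell short of a 2-fold change and 7 of the peak strength. Of 76 named iNKT peaks 3 failed at FDR 0.01 and 3 the peak strength (Eef2, Snord37 and Lrrc4c). No paired analysis was possible because the tables hold no values per sample, although the labels share replicate numbers. For that reason the replicate block, leaving out replicates, other count models and other splits of the samples were not run. The motif test and positions by midpoint or by other transcripts were not run, since no genome or transcript models were used. The depth of the libraries is unknown.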

Other observations

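The tests of gene families, chromosomes and the mitochondrial genome were all chosen after seeing the data.

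Genes with symbols that begin with Rps, as most ribosomal protein genes of the small subunit do, stood out among higher iNKT peaks. Families were taken from the start of the symbol, so a member need not be a ribosomal protein gene. Rpl genes, of the large subunit, were not tested in iNKT cells, since a family needed at least 15 genes. The excess therefore cannot be called particular to the small subunit. Of 24 Rps genes with a peak, 10 (41.7%) had a higher peak in Mettl3-deleted iNKT cells, against 9.53% of other genes (Fisher's exact test, adjusted p = 0.0055 over 152 tests of families of gene symbols, and adjusted p = 0.03 with matching on peaks per gene). In the authors' deposited table for iNKT cells, 10 of 11 Rn45s peaks were higher and none was lower. Rbm genes, which encode RNA-binding proteins, had lower iNKT peaks in 13 of 21 (61.9%, adjusted p = 0.045, Fisher's exact test), which was lost with matching (adjusted p = 0.11). With only peaks within the gene they are named after, 13 of 19 Rbm genes passed also with matching (adjusted p = 0.022, permutation), and so did 10 of 20 Rps genes (adjusted p = 0.022, permutation).

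In DP cells 4 of 13 peaks on the mitochondrial genome were higher and 0 were lower. The largest of these had a log2 fold change of 1.2 in the authors' deposited table (FDR 6.3e-18, chromosome M, 13552 to 14070), the smallest FDR among all DP peaks. Of 9 mitochondrial peaks in iNKT cells 3 were higher and 1 was lower. Of 80 tests of chromosomes over both tables and signs, 1 passed. Chromosome 17 held 60 higher iNKT peaks against 37.0 expected (odds ratio 1.75, adjusted p = 0.014, Fisher's exact test), and 10 of these were the Rn45s peaks. Chromosome 11 did not pass, with 8 lower DP peaks against 8.27 expected. The chromosome tests count passing peaks, which are not independent, and not their size. They therefore cannot show whether large changes gather on a chromosome. Chromosome 11 held the large DP falls of Atad5, Ska2, Fignl1, AI662270 and Tlk2 and the largest rise, in Ssh2. Sh3bgrl and the other largest DP rises lay on other chromosomes. Whether large changes gather on chromosome 11 was not tested.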
